A study of Homo sapiens with 18 samples.

How the data were processed

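Messenger RNA was measured by sequencing of polyadenylated RNA (TruSeq, 750 ng of RNA per library) in 18 libraries of 3 cholangiocarcinoma cell lines, HuCCT1, YSCCC and KKU-100, each with a control hairpin or a hairpin against RNF213 and 3 biological replicates per group. Each deposited file covers 1 library and 36601 gene IDs of build GRCh38. Per the labels, the authors used FastQC 0.11.9, STAR 2.5.1b, Picard 1.139, StringTie 2.1.6, HTSeq 0.6.1p1 and DESeq2 1.34.0; which step made which column, the filters and the strand setting are not given in the sources used here. Per the file headers, the values are raw counts per gene, FPKM, TPM, a coverage signal, and counts that the authors scaled with DESeq2. The deposited scaled signal equals the raw count times 1 constant per library, between 0.873 and 1.13, by a check within each file. Only the raw counts entered the tests. The deposited FPKM and TPM were used for checks, and the coverage signal was not used.

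Library totals ran from 21056732 to 25502097 counts. Gene symbols and positions come from the files; 34616 of the IDs (94.6%) were found in GENCODE release 29, which gave gene types and 3' UTR sequence. The start or end of 32 genes differed between files, and 10 symbols are shared by a pair of IDs, which were kept apart.

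Each line was tested alone with edgeR 4.0.16 (quasi-likelihood F test, TMM factors, filterByExpr with its minimum count of 10 and minimum total of 15) under R 4.3.3, comparing 3 shRNF213 with 3 shControl libraries. P-values of the fits are two-sided and Benjamini-Hochberg adjusted over the genes tested, with 0.05 as threshold; those of lists are adjusted over the lists of a line, and counts adjusted over a list alone use its members only. A fit of all 18 libraries with 6 group means gave the mean effect of the hairpin and the 3 differences of effects between lines. Levels in CPM (counts scaled to library size) use TMM-scaled totals. The tests, the gene lists, the rule for named genes and the alternative settings were chosen before the data were examined. Replicate numbers were then checked for pairing: across 10460, 10704 and 10060 genes with a mean log2 CPM above 3, deviations of the shControl and shRNF213 libraries of the same number from their group means correlated at 0.787, 0.707 and 0.763 in HuCCT1 (replicates 1, 2 and 3), 0.817, 0.724 and 0.902 in YSCCC and 0.729, 0.599 and 0.407 in KKU-100, all above the minimum of 0.1 set for pairing. Some libraries of different number passed this minimum too. In YSCCC, shControl 2 with shRNF213 1 gave 0.655 and shControl 1 with shRNF213 2 gave 0.515. In KKU-100, shControl 3 with shRNF213 2 gave 0.120. The minimum alone thus does not single out the pairs, though each same-number value was the highest for its libraries. The replicate number as a block, chosen in advance as another setting, is therefore given beside each unpaired result. The alternatives run on top of the block were added after seeing the data. A single gene over 9 pairs was tested by an exact sign-flip permutation test, and 3 against 3 libraries by an exact permutation test, both without adjustment.

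The 28 gene lists were the interferon-stimulated, MHC class I, mesenchymal, epithelial junction and keratin, matrix protease, integrin and laminin, EGFR family, ERK output, STAT3 target, NF-kappaB, hypoxia, TGF-beta, YAP and TEAD, Wnt, Notch, cell cycle, cholesterol synthesis, fatty acid and lipid droplet, ATF4, endoplasmic reticulum chaperone, p53 target, angiogenic, biliary and mucin, hepatocyte, stromal and immune, neuroendocrine, mitochondrially encoded and replication-dependent histone genes. Lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Named genes were RNF213, up to 8 genes per direction and line with the largest fold change among called genes with a mean of at least 5 CPM and no overlap between arms, up to 4 called members per list and line, up to 10 genes per direction called in all lines, up to 5 genes per difference between lines, and genes called in opposite directions. The rule was applied to both fits, and some genes it selects are not reported here.

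In a search for motifs, 15868 words of 7 bases present in at least 100 genes were scored over the 11589 genes that were tested in all lines and have a 3' UTR of at least 50 bases (88.5% of 13098). The score of a gene was the signed root of its F statistic in the paired fit, limited at the extreme percentiles, after a regression on UTR length, GC share and expression level. A word's z compares the mean score of genes with and without it, and a word was chosen on 2 lines and scored in the line left out. The hairpin sequences are not given in the sources used here, so the words were not matched to a hairpin. RNA of another line was assessed from genes with at least 100 CPM in every library of that line and a mean under 1 CPM in the other replicates of the line studied.

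Alternatives were DESeq2 1.42.0, limma-voom, RLE, upper-quartile and no normalization factors, no filter, a filter of 1 CPM in 3 libraries, an adjusted p of 0.01, an absolute log2 fold change of at least 1, all 18 libraries in 1 fit, the replicate block and each library or pair left out. The 6 libraries of a line were split in every other way into 3 and 3, and 60 splits were drawn for the joint fits and 100 for genes shared by the lines. The tests were tested on simulated data with planted changes. The simulation took its spread from the paired fits and added random replicate effects of the same SD for all genes. In the unpaired fits 100%, 77.6% and 59.7% of genes with a 2-fold change were recovered at the depth of HuCCT1, YSCCC and KKU-100. The paired fits recovered 100%, 100% and 94.0%. The unpaired spread of the real data was not set, so the unpaired shares may be too high. Planted replicate effects also favour the paired fits by construction. At 1.5-fold, 32.8%, 4.48% and 5.97% were recovered unpaired and 88.1%, 86.6% and 49.3% paired. The false share among calls of the line fits was 0% to 8.57%, and camera called 0 of 27 random lists per line. Random lists do not stand for lists whose members vary together. The false calls of camera on the real lists were therefore not tested by the simulation. Estimated correlations of the real lists in the paired HuCCT1 fit ran from -0.233 to 0.983. Other splits of the real pairs called 4 to 6 lists in HuCCT1, 4 to 6 in YSCCC and 5 to 9 in KKU-100. The real split called 8, 4 and 5. A planted word reached z = -9.65 in the line left out, and data without one 0.633. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps. Histone, HLA and mucin genes share reads with similar copies, and their values are uncertain.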

Results

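RNA was sequenced from 3 human cholangiocarcinoma cell lines that carried either a short hairpin RNA against RNF213 (shRNF213) or a control hairpin (shControl), both delivered by lentivirus as stable lines. Cholangiocarcinoma is a cancer of the bile duct epithelium, and RNF213 encodes a large cytosolic ubiquitin ligase with ATPase modules. Per the labels, HuCCT1 derives from bile duct, YSCCC from liver and KKU-100 from biliary tract; KKU-100 grew in another medium than the other lines, so line and medium differ together. The 6 groups held 3 biological replicates each, 18 libraries of polyadenylated RNA in all. Library totals ran from 21056732 to 25502097 counts over 36601 gene IDs, 4884 of which had 0 counts in all 18 libraries. Mitochondrial transcripts took 1.61% to 2.76% of the counts. The comparisons ask which transcripts differ with the RNF213 hairpin in each line, on average over the lines, and between lines; the series title frames RNF213 in terms of local invasion. Libraries of the same line that share a replicate number resembled each other, so each comparison is given unpaired, as fixed in advance, and with the replicate number as a block (paired). Genes said to have risen or fallen in a line passed the paired test at an adjusted p below 0.05 unless the unpaired test is named.

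RNF213 transcript was lower in the shRNF213 library than in the shControl library of the same replicate number in 9 of 9 pairs. RNF213 (ENSG00000173821) spans 80260866 to 80398786 on the plus strand of chromosome 17 (GRCh38). It went from 679.5 ± 476 to 321 ± 80.9 CPM (SD, n = 3 each) in HuCCT1, from 477 ± 87.5 to 214 ± 48.3 CPM (SD, n = 3 each) in YSCCC and from 1118 ± 134 to 568 ± 56.2 CPM (SD, n = 3 each) in KKU-100. Over the 9 pairs the mean log2 ratio was -1.01 (SD 0.41), or 2.02-fold lower; an exact two-sided sign-flip permutation test gave p = 0.00391, the smallest that 9 pairs allow. Within a line, exact two-sided permutation tests of 3 against 3 libraries gave p = 0.2 in HuCCT1 and p = 0.1 in both other lines, where 0.1 is the smallest p possible. In the fits across all genes the unpaired log2 fold changes of RNF213 were -1.08, -1.15 and -0.98 in HuCCT1, YSCCC and KKU-100, with adjusted p = 1.00, 0.883 and 0.362. Paired, RNF213 fell in YSCCC (-1.16, SE 0.13, adjusted p = 0.000307) and in KKU-100 (-0.97, SE 0.15, adjusted p = 0.0462), and stayed outside the threshold in HuCCT1 (-0.89, SE 0.18, adjusted p = 0.136). The HuCCT1 shControl library of replicate 2 held the most RNF213 counts of all 18 libraries, 26931, and without it the unpaired HuCCT1 value was -0.33. The shRNF213 library of replicate 2 was also the highest of its HuCCT1 arm (415 CPM against 271 and 278). Interferon-stimulated genes, summed without RNF213, were higher in both libraries of this replicate, as given below. A link between the 2 was not tested. Without 1 HuCCT1 pair the paired value passed, at adjusted p = 0.0339, 0.000992 and 9.37e-07 without replicate 1, 2 and 3. Such fits leave few degrees of freedom, so these p-values lean on the spread borrowed across genes and add no weight. The pairs left without replicate 3 fell unequally, from 388 to 271 and from 1229 to 415 CPM. In KKU-100 the call was lost without replicate 1 (adjusted p = 0.0663) or replicate 3 (0.251). The antisense gene RNF213-AS1 (minus strand, 80351828 to 80415168) overlaps RNF213 and had 42 to 126 counts per library; the strand setting of the counting is not given in the sources used here, so reads in the overlap are not assigned with certainty.

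**Figure D1:**
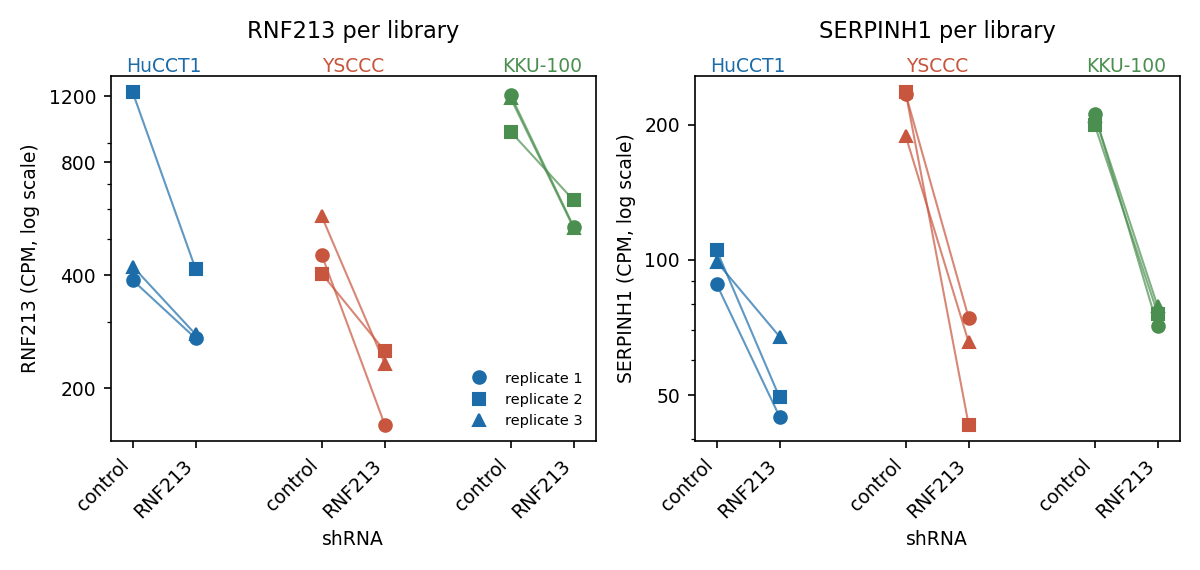
RNF213 and SERPINH1 in CPM (counts scaled to library size, log scale) in each library, with lines joining the shControl and shRNF213 libraries of the same replicate number in HuCCT1, YSCCC and KKU-100. In 9 of 9 pairs both genes were lower in the shRNF213 library, with mean log2 ratios of -1.01 for RNF213 and -1.40 for SERPINH1.

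The differences between replicates of a line included 2 coordinated programs that did not follow the hairpin. In HuCCT1, the summed level of the interferon-stimulated genes, the antiviral response set, was 13258 CPM in the shControl and 13050 CPM in the shRNF213 library of replicate 2. The mean over the other HuCCT1 libraries was 2139 CPM, so replicate 2 was 6.15-fold higher. In YSCCC, the endoplasmic reticulum chaperones and the ATF4 amino acid response genes, which serve protein folding and amino acid supply, summed to 20126 CPM in the shControl and 18631 CPM in the shRNF213 library of replicate 3. The other YSCCC libraries averaged 9873 CPM, which put replicate 3 higher by a log2 ratio of 0.97. These states entered the unpaired spread of the genes concerned, and the paired fits took them out where both arms shared them. Replicate differences were not confined to these programs. Log2 counts of YSCCC replicates 1 and 2 correlated across genes at 0.990 in shControl and 0.984 in shRNF213. Replicate 3 correlated with them at 0.919 to 0.928 within the arms. In KKU-100, libraries of the same number also deviated alike across genes (0.729, 0.599 and 0.407 for replicates 1, 2 and 3).

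**Figure D2:**
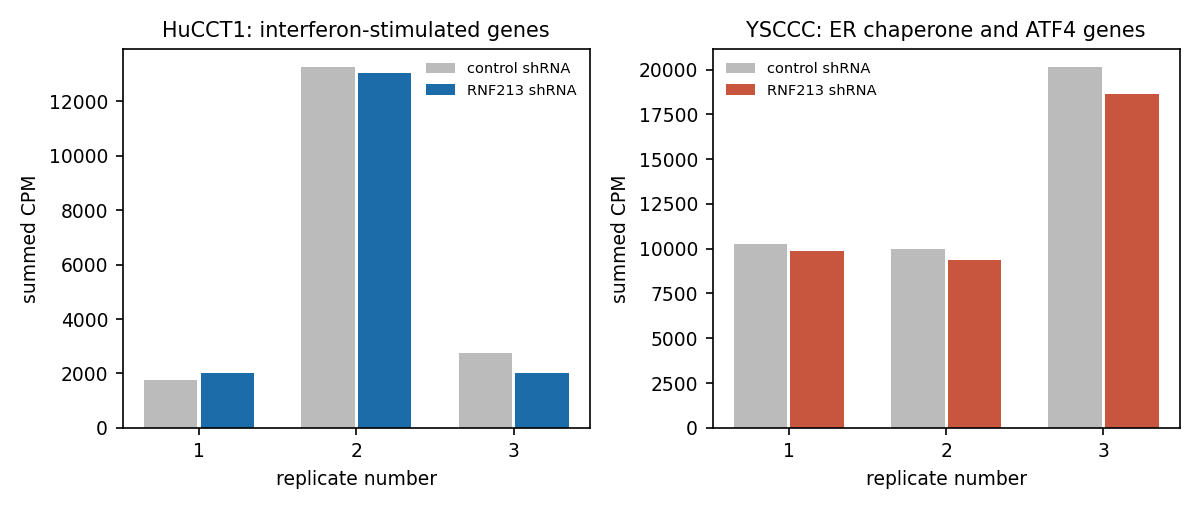
Summed CPM (counts scaled to library size) per library of the interferon-stimulated genes in HuCCT1 and of the endoplasmic reticulum (ER) chaperone and ATF4 genes in YSCCC, by replicate number, with grey bars for shControl and coloured bars for shRNF213. Both HuCCT1 libraries of replicate 2 lie at 13050 CPM or above, and both YSCCC libraries of replicate 3 at 18631 CPM or above.

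In HuCCT1, SERPINH1, LOX, TNFSF18 and VGLL1 fell with the RNF213 hairpin, and STARD3NL and BEX3 were among the genes that rose. SERPINH1, the collagen-specific chaperone of the endoplasmic reticulum, went from 97.6 ± 8.51 to 53.9 ± 12.01 CPM (SD, n = 3 each), and LOX, the lysyl oxidase that cross-links collagen and elastin, went from 35.7 ± 4.75 to 20.5 ± 3.29 CPM (SD, n = 3 each). TNFSF18, a ligand of the tumour necrosis factor family, fell by the widest margin among the named genes, at a log2 fold change of -1.45 (adjusted p = 0.0215), and VGLL1, a TEAD cofactor, fell at -0.67. Genes that rose included STARD3NL, a late endosomal protein (1.06), BEX3 (1.05), the sialyltransferase ST6GAL1 (1.02), the phospholipase PLCB4 (1.02) and the neutrophil chemokine CXCL5 (1.02). HINT2, CMBL, SRPRA, ENO2 and MCM7 rose by 0.92, 0.84, 0.81, 0.68 and 0.64. Of 15747 genes tested, 18 rose and 4 fell in the paired edgeR fit, and DESeq2 with the same block called 112 (70 higher, 42 lower). Unpaired, edgeR called 0 genes and limma-voom 0, DESeq2 called 24, and 388 genes had an unadjusted p under 0.05. Without replicate 1, LOX, MCM7, PLCB4 and VGLL1 lost their calls; the paired count was 18, 177 and 335 without replicate 1, 2 and 3 (13, 117 and 174 of these higher).

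Among the gene lists in HuCCT1, replication-dependent histone genes lay lower than other genes and cell cycle genes lay higher. The 13 tested histone genes had a median log2 fold change of -0.31 (camera adjusted p = 0.000245; adjusted p = 0.816 with an estimated correlation); 0 fell among all genes and 2 fell adjusted over the list alone. Histone genes share sequence with near-identical copies, so their counts are uncertain. The libraries were made from polyadenylated RNA, so the histone values here and in the other fits cover polyadenylated transcripts only. Of the 40 cell cycle genes, which encode replication and mitosis factors, 33 had positive values (median 0.10, adjusted p = 0.00112; 0.816 with an estimated correlation); the helicase subunit MCM7 rose, and 4 rose adjusted over the list alone. The ATF4 genes had a median of -0.19 (adjusted p = 0.00131; 0.816 with an estimated correlation; 0 of 24 fell, 4 adjusted over the list alone) and the YAP and TEAD targets one of -0.15 (adjusted p = 0.00167; 0.816 with an estimated correlation; 0 of 24 fell, 0 adjusted over the list alone). The interferon-stimulated genes had a median of -0.16 (adjusted p = 0.0155; 0.846 with an estimated correlation; 0 of 38 fell, 2 adjusted over the list alone). Higher medians were found for 5 neuroendocrine genes (0.32, adjusted p = 0.00153; 0.816 with an estimated correlation, where 1, the neuronal enolase ENO2, rose in all genes and in the list alone). So were those of 26 biliary and mucin genes (0.14, adjusted p = 0.0367; 0.816 with an estimated correlation; 0 changed, and 2 rose and 1 fell adjusted over the list alone) and 25 cholesterol synthesis genes (0.09, adjusted p = 0.0494; 0.846 with an estimated correlation; 0 changed, 2 rose adjusted over the list alone). The histone list kept its call without any 1 replicate. The cell cycle, ATF4, cholesterol and biliary lists lost theirs without replicate 1, the YAP and biliary lists without replicate 2, and the interferon, neuroendocrine and cholesterol lists without replicate 3. With the genes that hold a word of the 3' UTR search left out, the interferon and biliary lists were not called. The neuroendocrine list then had fewer than 5 members, as ENO2 holds a word, and was not tested. By direction fry called 0 lists in either fit, and regardless of direction 3 paired and 0 unpaired. The unpaired fit called 5 lists, all but the interferon-stimulated, biliary and cholesterol lists. The other 20 lists, the epithelial-mesenchymal, junction, protease, integrin and EGFR lists among them, had paired adjusted p = 0.218 to 0.963.

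In YSCCC, SERPINH1, FN1 and ITGA2 were among the genes that fell, and BMP3, CP and AGR2 among those that rose. SERPINH1 went from 219.8 ± 26.7 to 61.0 ± 16.2 CPM (SD, n = 3 each), and FN1, which encodes the matrix protein fibronectin, went from 530.0 ± 77.8 to 219 ± 47.5 CPM (SD, n = 3 each). ITGA2, a collagen receptor subunit, went from 606 ± 169.5 to 280.5 ± 105 CPM (SD, n = 3 each), while the growth factor BMP3 rose from 16.0 ± 6.65 to 46.0 ± 17.5 CPM (SD, n = 3 each). Others that fell were JCAD, a cell junction protein (-1.98), the endogenous retroviral envelope gene ERVV-2 (-1.72), the microfibril gene FBN2 (-1.56), the secretory coat subunit SEC23A (-1.34), the transcription factor KLF13 (-1.33) and the kinase NUAK2 (-1.33). CP, the copper carrier ceruloplasmin, rose by 3.31 from a low level (from 0.878 ± 0.426 to 9.88 ± 9.18 CPM (SD, n = 3 each)); LHFPL6 (1.88), the secretory disulfide isomerase AGR2 (1.70), GNG11 (1.57), ZNF804A (1.47), the matricellular factor CCN2 (1.44) and PEG10 (1.39) also rose. The highest adjusted p among these genes was 0.00175, for CCN2. Of 16932 genes tested, 625 rose and 772 fell in the paired fit, and paired DESeq2 called 1224 genes. Unpaired, edgeR called 0 genes and limma-voom 0, DESeq2 called 61, and 802 genes had an unadjusted p under 0.05. The paired count was 313, 530 and 1856 without replicate 1, 2 and 3; of 101 genes besides RNF213 named by the rule in this line, 51, 35 and 8 lost their calls in turn, among them COL17A1 and FGF1 without replicate 1 or replicate 2.

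Integrin and laminin genes and histone genes of YSCCC lay lower than other genes, and cell cycle genes lay higher. Of 26 integrin and laminin genes, which anchor cells to the basement membrane, 11 fell and 1 rose (1 rose and 14 fell adjusted over the list alone), with a median of -0.24 (camera adjusted p = 0.00636; adjusted p = 0.627 with an estimated correlation). ITGB3 (-1.85), ITGA2 (-1.13) and COL17A1 (-1.04) fell and the laminin chain LAMA4 rose (1.22); without replicate 1, ITGB3 and COL17A1 lost their calls. All 13 histone genes had negative values (median -0.74, adjusted p = 3.84e-06; 0.627 with an estimated correlation), and 8 fell, 11 adjusted over the list alone, among them HIST2H2BE. HIST1H1E, HIST1H4H (-0.87) and HIST1H2BC (-0.80) fell too and lost the call without replicate 1 or 2. Of 40 cell cycle genes 35 had positive values (median 0.19, adjusted p = 0.000913; 0.627 with an estimated correlation). MCM7 (0.97), E2F1 (0.42), TPX2 (0.40) and MCM4 (0.36) rose, 8 adjusted over the list alone; the last 3 lost their calls without replicate 1 or 2, and MCM4 without replicate 3. Of 22 endoplasmic reticulum chaperone genes 3 fell (DNAJC3 -0.61, HERPUD1 -0.54, SEL1L -0.53) and 1 rose (SEC61B 0.71), or 4 and 1 adjusted over the list alone. That list had a median of -0.14 (adjusted p = 0.0124; 0.627 with an estimated correlation) and is among the genes that were higher in replicate 3 (log2 ratio 0.97); its call was lost without replicate 3. Unpaired, 2 lists passed, the histone and integrin lists; fry called 0 by direction in either fit, and regardless of direction 18 paired and 1 unpaired.

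The other invasion and signalling lists of YSCCC did not pass as lists, though members changed. In the mesenchymal list 4 of 19 genes fell (5 adjusted over the list alone; list adjusted p = 0.0835), namely FN1 (-1.29), SPARC (-1.27), the fibronectin receptor subunit ITGA5 (-0.67) and LOXL2 (-0.46, call lost without any 1 replicate). Of 31 epithelial junction genes 6 fell and 2 rose (8 and 2 adjusted over the list alone), with DSG2 at -0.68, DSP at -0.60, TJP1 at -0.57 and TJP3 at 0.73. Of 27 matrix protease genes 7 fell and 2 rose (9 and 3 adjusted over the list alone): ADAM9 rose (0.78), as did MMP3 from under 1 CPM (2.26), and ADAMTS1 (-1.07) and SERPINB5 (-0.99) fell. EGFR and its ligand EPGN fell by smaller amounts (-0.30 and -0.62), while the immediate early genes FOS (0.87) and EGR1 (0.67) and ETV1 (0.71) rose; without replicate 1, DSP, ADAMTS1, MMP3, EGFR, EPGN, EGR1 and ETV1 lost their calls, as did EGFR, EPGN and ETV1 without replicate 2. NF-kappaB genes showed 6 falls and 1 rise among 32 (10 and 3 adjusted over the list alone), with IL32 at -1.52, LTB at -2.10, TNFAIP3 at -0.90 and RELB at -0.50. STAT3 targets showed 5 falls and 2 rises among 24 (5 and 2 adjusted over the list alone), with the immune checkpoint ligand CD274 at -1.03, IL6R at -0.60, BCL2L1 at -0.47 and PIM1 at 0.46; CD274, IL6R, BCL2L1, PIM1 and RELB lost their calls without replicate 1, the last 3 also without replicate 2. Of 38 interferon-stimulated genes IFI44L (0.93) and IFI44 (0.63) rose, the same 2 counts adjusted over the list alone, and both calls were lost without replicate 1 (IFI44L also without replicate 2 or 3). Over the 24 lists that did not pass in YSCCC, adjusted p ran from 0.0716 to 0.990.

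In KKU-100, SLC6A14, IL33 and TGFA rose, and the chemokine CCL5 and the interferon-induced genes IFIT2 and RSAD2 fell. SLC6A14, an importer of neutral and cationic amino acids, went from 22.9 ± 5.47 to 188 ± 61.4 CPM (SD, n = 3 each), 8.11-fold higher. SERPINH1 went from 207 ± 6.15 to 75.4 ± 3.89 CPM (SD, n = 3 each), and these were the 2 genes that passed unpaired as well (adjusted p = 0.0227 for each). IL33, an alarmin cytokine, rose from 6.25 ± 4.10 to 41.9 ± 22.1 CPM (SD, n = 3 each), and TGFA, a ligand of EGFR, from 13.7 ± 4.55 to 45.5 ± 13.9 CPM (SD, n = 3 each). The peptidase ANPEP (2.36), RTN1 (2.81), the matrix protein ABI3BP (2.29), CYP4F12 (2.01), CCDC170 (1.94) and ANXA10 (1.82) rose, as did ITGB4 (1.19), IL1A (0.99), SEMA3C (0.95) and the co-receptor NRP1 (0.92). The chemokine CCL5 fell by the widest margin among the named genes (-1.91), and TM4SF1 (-1.08), STAMBPL1 (-1.02) and C15orf48 (-0.92) fell as well. Of 14915 genes tested, 45 rose and 21 fell in the paired fit, and paired DESeq2 called 430 genes. Unpaired, edgeR called 2 genes, limma-voom 2 and DESeq2 93, and 966 genes had an unadjusted p under 0.05; the unpaired edgeR count was 5 without the shControl library of replicate 1 and 0 without any 1 of the other 5 libraries. The paired count was 420 without replicate 2 and 9 without replicate 3, where RNF213 and 20 of the 25 other named genes lost their calls and SLC6A14, SERPINH1, IL33, RTN1 and TGFA kept them; without replicate 1, RNF213, IL1A, OASL, CPE, SFXN3 and GALNT10 lost theirs.

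Interferon-stimulated genes lay lower in KKU-100 and cell cycle genes higher. Of 39 interferon-stimulated genes 35 had negative values (median -0.21, camera adjusted p = 8.43e-06; adjusted p = 0.95 with an estimated correlation). IFIT2 (-1.41), RSAD2 (-1.24) and OASL (-0.996) fell, and 7 fell adjusted over the list alone. Cell cycle genes were positive in 40 of 40 (median 0.80, adjusted p = 5.65e-08; 0.95 with an estimated correlation), but 0 passed singly, also adjusted over the list alone. Cholesterol synthesis genes had a median of -0.53 (adjusted p = 0.000649; 0.95 with an estimated correlation), with 22 of 24 negative, 0 falling and 1 falling adjusted over the list alone. Integrin and laminin genes had a median of 0.25 (adjusted p = 0.0118; 0.95 with an estimated correlation); of 23, ITGB4 alone rose, and 6 rose and 1 fell adjusted over the list alone. The 13 mitochondrially encoded genes had a median of 0.23 (adjusted p = 0.0118; 0.95 with an estimated correlation), and 0 passed singly, also adjusted over the list alone. The paired integrin call was lost without replicate 1 or 2, the mitochondrial call without replicate 1 or 3 and the cholesterol call without replicate 3. The unpaired fit called the same 5 lists, fry called 0 by direction or regardless of it, and the other 23 lists had paired adjusted p = 0.235 to 0.961.

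**Figure D3:**
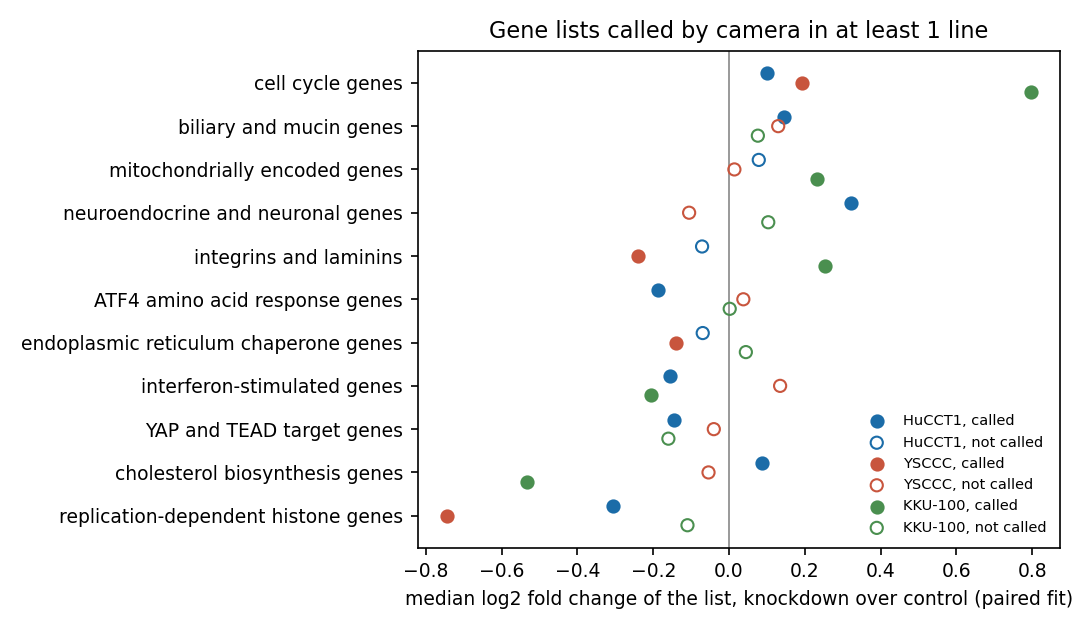
Median log2 fold change (paired fit, shRNF213 over shControl) of each gene list that camera called in at least 1 line, with filled points for called lists and open points for the others, coloured by cell line; with an estimated inter-gene correlation 0 lists were called in each line. Cell cycle genes had positive medians in all 3 lines (0.10, 0.19 and 0.80 in HuCCT1, YSCCC and KKU-100).

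SERPINH1 was the one gene that fell in all 3 lines in the paired fits. SERPINH1 (ENSG00000149257; chromosome 11, 75562056 to 75572783, plus strand) had paired log2 fold changes of -0.87, -1.87 and -1.46 in HuCCT1, YSCCC and KKU-100 (SE 0.11, 0.15 and 0.11; adjusted p = 0.0272, 4.08e-05 and 0.00445). It was lower in 9 of 9 pairs (mean -1.40, SD 0.53, 2.65-fold lower), a description of the pairs on which it was picked, and its paired calls held without any 1 replicate. With independent lines the expected number of such genes was 0.000198; the unpaired fits gave 0 shared genes, and 1 by DESeq2. RNF213, FAM114A2 and PIP4K2A were among genes that fell in 2 lines, and 19 genes rose in at least 2, among them STARD3NL, ST6GAL1, BEX3, HINT2 and MCM7, a set chosen after their values were seen. HuCCT1 and YSCCC shared 13 genes that rose, against 0.561 expected for independent lists. Of 16 HuCCT1 genes that rose and have a listed UTR, 15 hold GCTAATA, a word of the 3' UTR search. The overlap thus does not separate an effect of RNF213 loss from one through that word. Across 13098 genes, which are not independent replicates, the paired log2 fold changes correlated weakly between lines (Pearson 0.240 for HuCCT1 and YSCCC, 0.0999 for HuCCT1 and KKU-100, 0.0407 for YSCCC and KKU-100; Spearman 0.219, 0.0886 and 0.0187).

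Averaged over the lines, NUAK2, STX3 and SEC23A fell beside RNF213 and SERPINH1, and HPSE, BEX3 and STARD3NL rose. In the unpaired fit of all 18 libraries 12 of 19143 genes were lower, with log2 fold changes from -1.39 to -0.41: SERPINH1 (-1.39, adjusted p = 1.46e-05), ZCCHC24 (-1.11), RNF213 (-1.07, adjusted p = 0.0372), the kinase NUAK2 (-0.88), the membrane fusion protein STX3 (-0.86), FAM114A2 (-0.76), the secretory coat subunit SEC23A (-0.75) and the ubiquitin ligase adaptor FBXW11 (-0.69), with STYX, PIP4K2A, AKAP10 and MAP4K5 below these in size. Another 16 were higher (0.42 to 2.60): PLPP4 (2.60) was followed by HPSE, the heparan sulfate-cleaving heparanase (0.85), BEX3 (0.83), STARD3NL (0.78) and HINT2 (0.69). Of the 12 lower genes 10 hold a 3' UTR word with GTATTC, and of the 16 higher ones 12 hold GCTAATA, the motifs of the word search. These genes were listed after the values were seen, as the rule for named genes covers the lines and their differences. Paired, 273 genes rose and 282 fell on average; DESeq2 called 122 unpaired and 1035 paired. The unpaired count was 9 without the YSCCC shRNF213 library of replicate 2, 46 without that of replicate 3, and lay between 11 and 18 without any 1 of 13 further libraries; the paired count was 226, 260, 251 and 288 without HuCCT1 replicate 1 or 2 or YSCCC replicate 1 or 2, and 1011 without KKU-100 replicate 2. Cell cycle genes were positive in 40 of 40 in the paired mean (median 0.36, adjusted p = 3.82e-09; 0.901 with an estimated correlation), where 3 rose. Histone genes were negative in 13 of 13 (median -0.26, adjusted p = 1.10e-05; 0.314 with an estimated correlation), where 2 fell and fry by direction gave adjusted p = 0.0113; regardless of direction fry called 23 lists paired and 2 unpaired. The mitochondrially encoded genes (0.11, adjusted p = 0.0202) and the interferon-stimulated genes (-0.06, adjusted p = 0.0471) passed too, with adjusted p = 0.901 for both with an estimated correlation; unpaired, the cholesterol list passed in place of the interferon list (4 lists, adjusted p = 0.913 with an estimated correlation).

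Genes that fell on average shared a short motif in their 3' untranslated regions (UTRs). Words of 7 bases were ranked in 2 lines and then scored in the line left out; in each of the 3 rotations the word most tied to lower genes held GTATTC (GTATTCA, AGTATTC or GTATTCT), with z = -5.60, -7.38 and -5.88 in HuCCT1, YSCCC and KKU-100. Among 11589 genes with a listed UTR, 2801 hold such a word, SERPINH1, RNF213, FN1, SPARC, ITGA2, DSG2, TJP1, IFIT2 and RSAD2 among them. Their mean paired log2 fold change lay -0.06, -0.04 and -0.03 from that of the other genes in HuCCT1, YSCCC and KKU-100. In the paired mean 150 of 266 genes that fell and have a listed UTR hold the word (56.4%), against 23.5% of genes not called; by line the genes that fell and hold it were 1 of 3 in HuCCT1, 229 of 579 in YSCCC and 8 of 19 in KKU-100. The words were chosen on these same fits, so these shares are a description and not a further test. Genes that rose shared GCTAATA, which 969 genes hold, STARD3NL, BEX3, ST6GAL1, CXCL5, HINT2, CMBL, SRPRA, ENO2 and MCM7 among them. Its z in the line left out was 13.4 in HuCCT1, 14.0 in YSCCC and 2.97 in KKU-100. Of 16 HuCCT1 genes that rose and have a listed UTR 15 hold it, against 8.25% of genes not called; in YSCCC 162 of 444 do, and in KKU-100 5 of 30 (16.7%, against 8.35%). The GCTAATA shift was smaller in HuCCT1 than in YSCCC (difference -0.10, z = -10.2) and larger in YSCCC than in KKU-100 (0.11, z = 7.74), while HuCCT1 minus KKU-100 gave 0.01 (z = 1.05). The GTATTC shift was further below 0 in HuCCT1 than in YSCCC (-0.02, z = -2.93) or KKU-100 (-0.03, z = -4.19), and YSCCC minus KKU-100 gave -0.01 (z = -1.51), with z taken across genes. These shifts are not adjusted for UTR length, GC share or expression, and the order of the lines depends on the measure: in the adjusted scores HuCCT1 stands far above KKU-100 for GCTAATA (13.4 and 2.97) and is the weakest line for GTATTCA and AGTATTC. With the genes that hold either word left out, the paired counts were 0 in HuCCT1, 708 in YSCCC, 33 in KKU-100 and 122 in the mean.

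**Figure D4:**
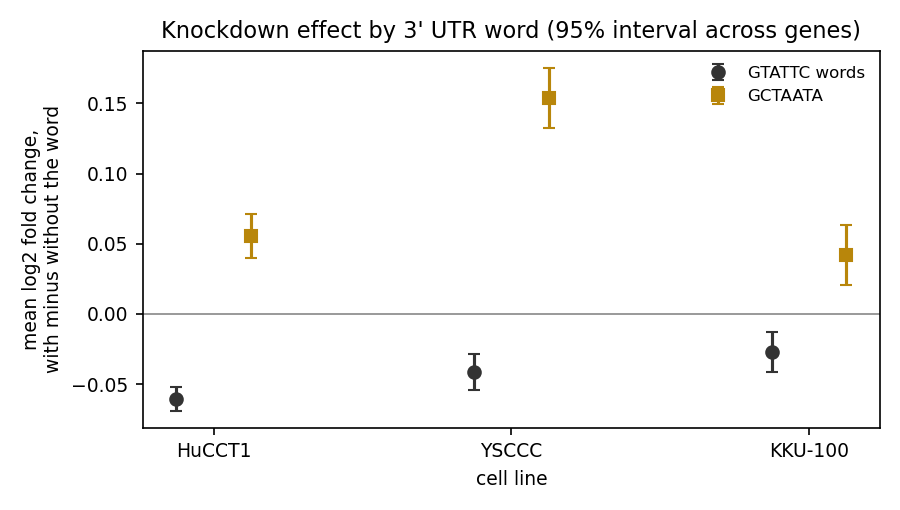
Mean paired log2 fold change of genes whose 3' UTR holds a GTATTC word (circles) or GCTAATA (squares) minus that of genes without it, with 95% intervals across genes, for each cell line. The GTATTC shifts were -0.06, -0.04 and -0.03 and the GCTAATA shifts 0.06, 0.15 and 0.04 in HuCCT1, YSCCC and KKU-100.

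Single genes passed the paired test of a difference between lines, though other splits of the pairs do not exclude chance for their number. SH3RF2, a ring finger protein with SH3 domains, fell in YSCCC (-1.30) and rose in KKU-100 (1.31), a paired difference of -2.61 (adjusted p = 0.000339). The prohormone-processing enzyme CPE (-0.97 and 1.05), SFXN3 (-0.79 and 0.84) and GALNT10 (-0.39 and 0.71) were also opposite in these lines; CPE and GALNT10 lost the YSCCC call without replicate 1, GALNT10 also without replicate 2; in KKU-100, CPE, SFXN3 and GALNT10 lost it without replicate 1 or 3, and SH3RF2 without replicate 3. TGFA rose in KKU-100 by 1.73, with -0.03 in HuCCT1 and -0.25 in YSCCC, and its differences were -1.76 for HuCCT1 minus KKU-100 and -1.98 for YSCCC minus KKU-100. AGR2 and PEG10 rose in YSCCC and had -0.01 and 0.27 in HuCCT1 (differences -1.71 and -1.11), and the actin-bundling FSCN1 fell in YSCCC (-1.11) against 0.27 in HuCCT1 (1.37). The SERPINH1 effect did not pass a test of difference between lines (paired adjusted p = 0.118, 0.287 and 0.324), nor did that of RNF213 (0.830, 0.974 and 0.773). Paired, 2 genes were higher and 7 lower for HuCCT1 minus YSCCC, 14 and 31 for HuCCT1 minus KKU-100, and 190 and 313 for YSCCC minus KKU-100. Unpaired, edgeR called 0 in each, DESeq2 1, 2 and 49, and 344, 621 and 1108 genes had an unadjusted p under 0.05. Leaving out 1 pair moved these paired counts to 0 to 44, 4 to 290 and 156 to 839, with the highest each time without KKU-100 replicate 2 and the lowest without HuCCT1 replicate 2, YSCCC replicate 1 or 2 (0), without HuCCT1 replicate 1 or 2 (4) and without YSCCC replicate 2 (156).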

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

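The paired form of the differences between lines was reported after the libraries were seen to pair by replicate number, and the alternatives on top of it were added then; the counts over other splits were chosen in advance. Results appear here because the hairpin's effect differed between 2 lines in a test of the difference itself, or because a deposited column outside the comparisons held a signal.

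The paired effect differed for 9 genes between HuCCT1 and YSCCC, for 45 between HuCCT1 and KKU-100 and for 503 between YSCCC and KKU-100. For HuCCT1 minus YSCCC the named genes were AGR2 (log2 difference -1.71), PEG10 (-1.11), FSCN1 (1.37), the membrane mucin MUC3A (-1.92) and KDELR3, a retrieval receptor of the endoplasmic reticulum (1.04), each at adjusted p = 0.0263. MUC3A reads are shared with similar mucin genes. For HuCCT1 minus KKU-100 they were TGFA (-1.76, adjusted p = 0.00254), ANPEP (-2.46), EXPH5 (-2.29), AMIGO2 (-1.40) and TRNP1 (1.43, adjusted p = 0.0125). For YSCCC minus KKU-100 they were SH3RF2 (-2.61, adjusted p = 0.000339), TGFA (-1.98), SFXN3 (-1.63), PEG10 (1.48), SLC6A14 (-3.08), CPE (-2.02) and GALNT10 (-1.10, adjusted p = 0.00362). EXPH5 rose in YSCCC (0.49) and KKU-100 (2.38), and AMIGO2 did too (0.65 and 1.47).

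Over 60 splits of the pairs, 4 gave as many genes as the 9 for HuCCT1 minus YSCCC (highest other 189), so chance is not excluded. For HuCCT1 minus KKU-100, 2 of 60 gave 45 or more, the real one included, and 1 other split called 193. Splits of the pairs stand for no hairpin effect in any line and not for equal effects in 2 lines. They therefore cannot exclude chance for this difference. For YSCCC minus KKU-100, 3 of 60 gave 503 or more (highest other 745), and chance is not excluded. The other splits with counts that large, 3, 1 and 2 of them, kept the real split or its mirror in at least 1 of the lines, so that an effect held in common then counts as a difference. Unpaired, 0 genes were called for each difference, so 60 of 60 splits give as many by construction and test nothing. The highest others were 41, 17 and 437, which could reflect a structure of the samples; the cause was not tested.

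A total of 20 genes had 0 counts in all 18 libraries and a deposited TPM of at least 1 in each of them. The TPM column was not used in the comparisons.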

How the results depend on the processing

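All alternatives on top of the replicate block, and the counts without genes that hold a UTR word, were chosen after seeing the data. Of 1392 alternatives of 140 named gene results, 1107 kept direction and call, 285 lost the call (138 without the block, 123 without a replicate) and 0 turned direction; of the alternatives of comparisons, 297 were the same, 158 moved, 9 gained and 4 lost a call. Where not stated, the cause was not tested; fewer replicates, stricter thresholds and other sets of tested genes act by construction. Scalings moved the median of all genes by less than 0.1. Alternatives for files without counts did not apply. In the simulated data, which held planted replicate effects, 1.5-fold changes were missed unpaired more often than paired.

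Unpaired, DESeq2 called 24, 61, 93 and 122 genes in HuCCT1, YSCCC, KKU-100 and the mean, and 1, 2 and 49 for the differences (HuCCT1 minus YSCCC, HuCCT1 minus KKU-100, YSCCC minus KKU-100); 1 gene was shared by the lines. The block gave 22, 1397, 66 and 555, then 9, 45 and 503, and 1 shared. All 18 libraries in 1 fit called 5 in YSCCC; no filter called 18 in KKU-100; an adjusted p of 0.01 left 0 in KKU-100 and 3 in the mean, and a log2 fold change of 1 left 4 in the mean. With libraries left out the counts were 0 to 0 in HuCCT1, 0 to 0 in YSCCC, 0 to 5 in KKU-100, 9 to 46 in the mean, 0 to 0, 0 to 1 and 0 to 9 for the differences and 0 to 0 shared.

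Paired, DESeq2 called 112 in HuCCT1, 430 in KKU-100, 1035 in the mean, 150, 290 and 1021 for the differences and 4 shared. No filter gave 117, 2160, 193 and 907, then 125, 273 and 894, and 4 shared. An adjusted p of 0.01 left 1, 497, 4 and 177, then 0, 3 and 82, and 0 shared; a log2 fold change of 1 left 7 in HuCCT1, 289 in YSCCC, 36 in the mean, 246 for YSCCC minus KKU-100 and 0 shared. All 18 libraries in 1 fit gave 8, 782 and 846, and 0 shared. In HuCCT1, upper-quartile factors gave 37 and no factors 38. Without the block the counts were 0, 0, 2 and 28, then 0, 0 and 0, and 0 shared; without genes holding a word, 0, 708, 33 and 122. With pairs left out they were 18 to 335, 313 to 1856, 9 to 420 and 226 to 1011, then 0 to 44, 4 to 290 and 156 to 839, and 1 to 4 shared.

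RNF213 passed unpaired with DESeq2 in YSCCC (-1.15) and KKU-100 (-0.98), without a filter in KKU-100 (-0.98) and with the block (-1.16 and -0.97); paired, it passed in HuCCT1 without a filter (-0.89) and lost the call without the block in YSCCC (-1.15) and KKU-100 (-0.98). Left-out libraries gave -1.36 to -0.33, -1.28 to -0.98 and -1.07 to -0.92 in HuCCT1, YSCCC and KKU-100 unpaired, and -1.09 to -0.56, -1.41 to -0.997 and -1.15 to -0.87 paired.

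For lists, an estimated correlation called 0 and fry 0 by direction in each line in both fits; regardless of direction fry called 3, 18 and 0 paired and 0, 1 and 0 unpaired. The unpaired counts became 8 in HuCCT1 and 4 in YSCCC with the block, and 1 in YSCCC without a filter or without word genes; the paired ones 5 in HuCCT1 without a filter, word genes or block, and 2 in YSCCC without the block. Left-out libraries gave 4 to 8, 3 to 6 and 2 to 8 lists unpaired, and 5 to 6, 3 to 8 and 4 to 5 paired.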

Other observations

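Other gene groups changed member by member in YSCCC, and these are descriptions of genes named by the rule. Angiogenic and hypoxia genes rose and fell: the lipase inhibitor ANGPTL4 rose (1.75), as did ANGPT1 (1.05), PDGFC (0.67) and PFKFB3 (0.47), and FGF1 (-0.87), P4HA2 (-0.45) and HK2 (-0.41) fell. Wnt ligands went both ways, with WNT7B (0.76) and WNT5A (0.66) higher and WNT10A (-0.94) lower; in the Notch list NOTCH1 (-0.56) and HES2 (-1.19) fell and MAML2 rose (0.45). TGF-beta genes were mixed, with TGFBR1 (-0.71) and COL1A1 (-0.61) lower and TGFB1 (0.47) higher. The biliary genes MUC1 (0.44), SPP1 (0.95), SOX4 (0.40) and MUC3A (1.01) rose, and so did the protease inhibitor SERPINA1 (0.99). Of 15 stromal and immune markers 4 rose and 4 fell (5 and 4 adjusted over the list alone; list adjusted p = 0.943), with COL3A1 (-1.17) and ITGAM (-1.62) lower and HLA-DRA (1.33) and PECAM1 (1.12) higher. Other genes that fell were the sterol regulator INSIG1 (-1.06) and the neuronal tubulin TUBB3 (-0.69), while the serine synthesis enzyme PHGDH rose (0.80). Of these genes PDGFC, WNT7B, WNT5A, TGFBR1, MUC3A, SERPINA1, COL3A1 and INSIG1 kept the call without any 1 replicate; HLA-DRA lost it without replicate 2, and each of the others without replicate 1.

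The word search over the 3 lines, the tests for RNA of another line and the counts over splits were set before their results were seen; the tests of the hairpin within a replicate, of a shared culture day, of base composition and of single lines were chosen only after the results were seen. Short hairpins can act on transcripts whose 3' UTRs match their seed, the bases next to the 5' end of the guide strand, in the manner of a microRNA. A candidate explanation of part of the genes that fell is such a match of the RNF213 hairpin: the weakest z of a GTATTC word in a line left out was -5.60, beyond the limit of -4 set before the search. Against base composition or UTR length alone, the most extreme z among orders of the same bases that lack GTATTC was -4.46. The GTATTC words reached -9.34 to -9.67 in the paired mean, a fit that shares its data with the choice of the words. Orders that hold GTATTC were left out of this comparison. GTATTCA (-9.43) and AGTATTC (-9.34) are orders of the same bases, and TGTATTC (-7.63) is an order of those of GTATTCT. RNF213 itself holds such a word, so an effect of RNF213 loss and one through the word cannot be separated for genes like SERPINH1 with 1 hairpin per target.

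For the genes that rose, a match of the control hairpin, which would lower those genes in the shControl libraries, is a candidate explanation in HuCCT1 (z = 13.4) and YSCCC (z = 14.0). In KKU-100, and so for the 3 lines together, it stays open: the z of 2.97 lies below the limit of 4 set before the search. Other orders of the bases of GCTAATA that lack both GCTAAT and CTAATA reached at most 3.54, against 13.8 for GCTAATA itself in the paired mean. This argues against base composition. AGCTAAT, an order of the same bases that overlaps the word in GCTAAT, reached 7.76. A higher response of these genes to RNF213 loss through some factor that binds the word was not tested, and the hairpin sequences were not used here.

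The states shared by both libraries of a replicate number are the third pattern; the log2 ratios of the arms, -0.0228 for the interferon-stimulated genes in HuCCT1 replicate 2 and -0.11 for the endoplasmic reticulum and ATF4 genes in YSCCC replicate 3, restate that both arms were high and test no cause. In HuCCT1 replicate 2, genes abundant in KKU-100 or YSCCC reached a median of -0.0151% or 0% of their level there, where 79.3% of KKU-100 RNA would be needed. In YSCCC replicate 3, genes of HuCCT1 or KKU-100 reached 0.0450% or 0.0110%, and RNA of the other lines is therefore excluded for both. A shared culture day or batch could account for them and cannot be told apart from a state of those cells, since the labels give no day; the arms of the replicate correlated at 0.707 in HuCCT1 and 0.902 in YSCCC.

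The counts of called genes were set beside those of other splits of the same libraries. Where 0 genes were called, every split gives as many by construction, and the splits test nothing. That holds unpaired for HuCCT1 and YSCCC (10 of 10 each, highest other 0) and for genes shared by the 3 lines (100 of 100, highest other 0). For HuCCT1, 1 of 4 splits of the pairs gave the 22 called paired (highest other 0). For YSCCC it was 1 of 4 paired (1397, highest other 0). For KKU-100 the figures were 2 of 10 unpaired (2, highest other 177) and 1 of 4 paired (66, highest other 0). The split that called 177 set both libraries of replicate 1 with the shRNF213 library of replicate 3 against the rest, which points to a structure of the samples. For gene lists, 8 of 10 and 1 of 4 splits called as many in HuCCT1 (5, highest other 11, and 8, highest other 6), 9 of 10 and 4 of 4 in YSCCC (2 and 9, 4 and 6), and 9 of 10 and 4 of 4 in KKU-100 (5 and 13, 5 and 9). Splits this few cannot give a share under 0.05. Paired, the real split called fewer lists than the median other split in YSCCC (4 against 5) and KKU-100 (5 against 9). Unpaired it did so in HuCCT1 (5 against 7), YSCCC (2 against 5) and KKU-100 (5 against 9). In these fits the number of lists called does not set the hairpin apart from other splits. For the mean effect 1 of 60 splits, the real one, was as large both unpaired (28, highest other 0) and paired (555, highest other 301). That is the smallest share 60 splits allow, so chance is unlikely but not excluded. The unpaired splits can set both libraries of a replicate number in the same group, unlike the real split, and are a weaker reference. For genes shared by the 3 lines in the paired fits, 1 of 100 combinations gave the 1 gene (highest other 0); the other splits of each line called 0 genes, so this too was fixed by construction and tests nothing.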
